A study of Mus musculus with 12 samples.

How the data were processed

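The study profiled poly(A) RNA of mouse oocytes from WT and Mtr4-null ovaries at day 14 and day 21. The labels name 12 samples, 3 per genotype and age. The design text speaks of duplicates, and it and the labels give 10 oocytes per sample. Per the labels' protocols, oocytes were lysed directly with oligo-dT primers and ERCC spike-in RNA, and libraries were made by Smart-seq2. Nothing in the labels says whether the samples of a group came from different animals.

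Per the submitters' processing notes, TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse build mm9 were used, with no role or order stated. The deposited table holds FPKM values, read fragments scaled to transcript length and library size, in 1 column per group, each the authors' mean over the libraries of that group. It has 23235 gene symbols and no ERCC rows. In the columns of WT day 14, WT day 21 and Mtr4-null day 14, 51.6%, 50.9% and 52.9% of the values above 0 end in repeating 3s or 6s, which is what a mean of 3 rounded numbers gives. In the Mtr4-null day 21 column none do, and of its 2211 values from 10 to 100 with 5 decimals 92.3% end in 5, which is what a mean of 2 gives. That column may therefore average fewer libraries than the labels list. The FPKM summed to 599453 in WT day 14, 595721 in Mtr4-null day 14, 603675 in WT day 21 and 649983 in Mtr4-null day 21. Values per library were not used here, so the depth of each library is unknown and no SD, interval or p-value can be given. FPKM are relative to the RNA of each library, so a difference in RNA content per oocyte between groups would not show.

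The design fixed before the data were examined called for limma-trend tests on 12 libraries, camera tests of gene lists, and refits without single libraries. None of these can be run on means. In their place, chosen after the data were seen, each contrast is the difference of log2(FPKM + 1) between 2 group means, for the 11913 genes with a mean FPKM of at least 1 over the 4 groups. Such a difference understates the fold of genes with low FPKM. Genes at least 2-fold apart, a log2 difference of 1, are counted, and this is a rule of size, not a test. For each of the 27 gene lists, the median log2 difference was placed among the medians of 10000 random lists of other genes with the same number of genes in each of 20 bins of mean log2 expression. Lists with fewer than 5 measured members got no percentile. The percentile describes these group means and is no p-value. On random lists drawn from the 11747 genes other than short RNA loci, unshifted lists of 20 genes fell above the central 95% in 3% and below it in 2.5% of 200 simulations at day 14, and in 3.5% and 4.5% at day 21. Lists of 20 genes shifted by 0.6 on the log2 scale were found above it in 100% of cases at day 14 and in 30.5% at day 21. Lists of that size can therefore go unseen at day 21, where single genes spread more widely.

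The lists covered RNA exosome and MTR4 partners, nuclear and imprinted long non-coding RNAs, snoRNA hosts, Gm models, Rik clones, histones, ribosomal proteins, oxidative phosphorylation, splicing factors, RNA polymerase subunits, oocyte transcription factors, zona pellucida and secreted factors, maternal effect genes, mRNA storage and decay, meiotic arrest, meiotic prophase, chromatin regulators, piRNA pathway, p53 response, unfolded protein response, interferon response, ion transport, growth signalling, endomembrane trafficking, early embryonic genes, granulosa markers, and theca, stromal, endothelial and blood markers. Some lists share members, such as Kit in growth signalling and secreted factors.

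Genes were named by a rule fixed before the data were examined, reduced to its parts that need no test. It takes the targeted gene, then the 8 largest rises and 8 largest falls of each genotype contrast (5 for age contrasts and the interaction) among genes with an FPKM of at least 5 in the higher group, 2 Gm or Rik genes in each direction, and up to 4 members of each list that differed 2-fold, or the most abundant members to make 2. Applied as fixed, the rule takes almost only short RNA loci. A second set without them, and without 25 symbols that a spreadsheet had turned into dates, was therefore added after the values were seen, and it gives most names in the text. The short RNA loci named are from the rule as fixed.

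Gene classes came from RefSeq symbols and synonyms of the GRCm38 assembly, which matched 11805 of the 11913 genes, 1216 of them by synonym. Exonic lengths, exon numbers and neighbouring genes came from GENCODE vM21 on the same assembly. The authors' build was mm9, so no coordinates are printed. Of the 220 genes the rule names, 215 were found in GENCODE and 117 overlap another gene there, 71 of them on the opposite strand. Dclre1c, for example, overlaps Suv39h2, and Snhg3 overlaps Rcc1. The former pair overlaps on opposite strands and the latter on the same strand. Reads from the shared stretch of such genes may be counted for either, so these values are uncertain.

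Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter beyond a value above 0, a minimum mean FPKM of 5, median-of-ratios scaling over 9805 genes above 1 FPKM in every group, and quantile normalization. Leaving out short RNA loci was added later. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.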

Results

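Poly(A) RNA was profiled in growing mouse oocytes collected at postnatal day 14 and in germinal vesicle oocytes collected at day 21. Wild-type (WT) oocytes were compared with Mtr4-null oocytes, which lack MTR4, the RNA helicase that feeds nuclear RNA to the RNA exosome for decay. The labels list 12 libraries in 4 groups of 3, each made from 10 oocytes by Smart-seq2, a full-length method that copies polyadenylated RNA and does not keep the strand. The values analysed here were 1 mean FPKM per gene and group, as averaged by the authors, for 23235 gene symbols. There was therefore no replicate error for any value below, no test could be run, and the depth of each library is unknown. Differences are described by size alone, on the log2(FPKM + 1) scale unless an FPKM is given, for the 11913 genes with a mean FPKM of at least 1 over the groups. A gene is counted as higher or lower when it differed at least 2-fold on that scale, and the WT change with age serves as a yardstick for the size of differences.

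Skiv2l2, the older symbol of Mtrex, which encodes MTR4, stood at 27.6 FPKM in WT and 1.57 FPKM in Mtr4-null oocytes at day 14, a 17.6-fold lower value. At day 21 it stood at 26.3 FPKM in WT and 3.86 FPKM in Mtr4-null oocytes, 6.80-fold lower. The part of the gene that was deleted is not given in the sources used here, so the remaining reads may lie outside it.

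The comparison at day 14 asked which transcripts differ without MTR4 in growing oocytes, and more of them were higher than lower in Mtr4-null oocytes. The heavy-metal binding protein gene Mt1 stood at 1.48 FPKM in WT and 640 FPKM in Mtr4-null oocytes. The long non-coding RNA AI506816 stood at 9.31 and 462 FPKM, and Snhg3, a non-coding host of small nucleolar RNAs, at 5.32 and 140 FPKM. Dclre1c, which encodes the nuclease Artemis, stood at 20.9 and 507 FPKM, Lrrc2 at 5.79 and 178 FPKM, and Ccdc48 at 1.49 and 67.5 FPKM. The ribosomal protein pseudogene Rplp2-ps1 stood at 0.804 and 64.0 FPKM. Rmrp, the RNA of the endoribonuclease RNase MRP, was listed at 0 in WT and at 32.1 FPKM in Mtr4-null oocytes. Among unnamed transcripts, 2900060B14Rik stood at 0.426 and 77.7 FPKM and Gm7616 at 2.17 and 82.0 FPKM.

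Fewer transcripts were lower at day 14. The neuropeptide gene Nmu stood at 9.05 FPKM in WT and at 0.745 FPKM in Mtr4-null oocytes. Fam162b stood at 9.85 and 1.09 FPKM, the calcium-binding protein gene Rgn at 16.1 and 2.63 FPKM, and the lipid hydrolase gene Pnpla3 at 66.7 and 14.1 FPKM. Oas1f stood at 24.2 and 5.22 FPKM, the ubiquitin ligase gene Nedd4l at 13.6 and 2.70 FPKM, and the amino acid transporter gene Slc6a15 at 8.64 and 1.47 FPKM. Among Rik symbols, 4930588N13Rik is now the protein-coding gene Tex26 and 2310069G16Rik is long non-coding. They stood at 55.3 and 13.9 FPKM in WT and at 11.4 and 4.03 FPKM in Mtr4-null oocytes. In all, 965 genes were at least 2-fold higher and 185 lower. Quantile normalization gave 706 higher and 321 lower, which takes the higher share from 83.9% to 68.7%. With a pseudocount of 0.1 in place of 1 the total was 1740 rather than 1150.

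**Figure D1:**
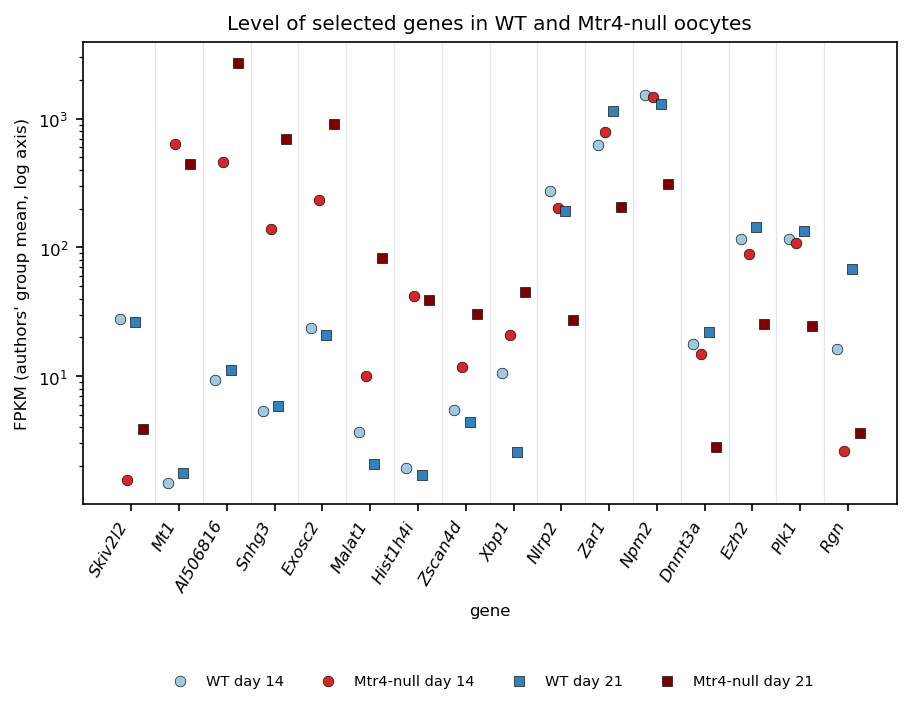
FPKM on a log axis (the authors' mean per group, no error available) of 16 genes named in the text and chosen for the plot after their values were seen, in WT and Mtr4-null oocytes at day 14 (circles) and day 21 (squares). Mt1, AI506816, Snhg3 and Exosc2 lie above WT in Mtr4-null oocytes at both ages, and Nlrp2, Zar1, Npm2, Dnmt3a, Ezh2 and Plk1 lie well below WT at day 21 but close to it at day 14.

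Classes of gene differed in the size of their shift, and at day 21 on the deposited scale also in direction. Of 587 long non-coding genes, 227 were higher and 18 lower at day 14, with a median log2 difference of 0.65. Of 10925 protein-coding genes, 604 were higher and 138 lower, with a median of 0.030. Of the pseudogenes, 27 were higher and 2 lower. At day 21 the long non-coding genes divided into 341 higher and 83 lower, with a median of 1.40, and the protein-coding genes into 1906 higher and 2920 lower, with a median of -0.34. Pseudogenes divided into 47 higher and 18 lower. The long non-coding median lay above the medians of all 10000 random lists of other genes matched on expression at both ages. The class was placed only with the filter on low FPKM, which 587 of its 1660 genes passed. That filter takes the mean of all 4 groups, so genes low in WT can pass it through their Mtr4-null values. The long non-coding median also kept its sign under the other scalings. Under median-of-ratios scaling and quantile normalization it stood at 0.58 and 0.40 at day 14 and at 1.69 and 1.33 at day 21. The protein-coding median was -0.024 and -0.11 at day 14 and -0.0066 and -0.32 at day 21, and under median-of-ratios scaling 2487 protein-coding genes were higher and 1851 lower at day 21.

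**Figure D2:**
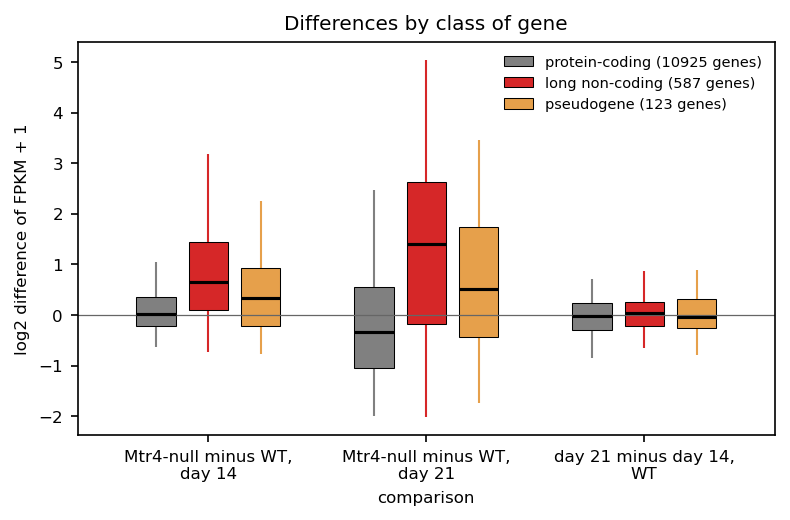
Log2 difference of FPKM + 1 for protein-coding, long non-coding and pseudogene transcripts in 3 comparisons of group means; boxes span the 25th to 75th percentile of genes, thick lines mark the median and thin lines reach the 5th and 95th percentile. The long non-coding medians are 0.65 at day 14 and 1.40 at day 21, against 0.030 and -0.34 for protein-coding genes (-0.024 and -0.0066 under median-of-ratios scaling), and each class sits near 0 in the WT age comparison.

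Several of the 27 gene lists drawn up before the data were examined stood apart at day 14. Among nuclear and imprinted long non-coding RNAs, 5 of 8 measured members were higher and none lower, among them Dleu2, Malat1 and Airn, with log2 differences of 1.34, 1.24 and 1.23. Under median-of-ratios scaling 4 were higher, and under quantile normalization 2. The other members of the 19 found did not pass the filter on low FPKM. Of 18 snoRNA host genes, 7 were higher and none lower, with Snhg9 at 12.6 FPKM in WT and 209 FPKM in Mtr4-null oocytes and Snhg4 at 0.650 and 16.4 FPKM. Of 27 replication-dependent histone genes, whose mRNAs normally end without a poly(A) tail, 13 were higher and none lower. Among them, Hist1h4i stood at 1.92 and 41.9 FPKM, Hist1h4c at 1.48 and 20.8 FPKM, and Hist2h4 at 2.21 and 22.6 FPKM. Histone H4 copies are near identical, so reads may be shared among them. Of 8 measured genes of the early embryonic (2-cell) list, 2 were higher and none lower, namely Zscan4c at 1.37 and 4.50 FPKM and Dub1 at 0.262 and 1.74 FPKM. Under quantile normalization none was higher. The filter on low FPKM kept 8 of 24 early embryonic genes and 27 of 68 histone genes. Genes low in WT can pass it through their Mtr4-null values. The models with Gm numbers divided into 58 higher and 11 lower of 321, and the Rik clones into 227 higher and 17 lower of 1012. Some of these symbols now belong to named protein-coding genes.

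The medians of these 6 lists, and that of 16 oocyte transcription factors, lay above the central 95% of expression-matched random lists. None of the 16 factors differed 2-fold, with Obox2 at 1025 and 836 FPKM and Zfp57 at 864 and 951 FPKM. The 84 cytosolic ribosomal protein genes and 76 oxidative phosphorylation genes lay below it, with medians 0.31 and 0.27 under that of all genes, or -0.091 and -0.092 relative to it under quantile normalization. Of the ribosomal protein genes 1 was higher, Rpl7l1 at 24.9 and 126 FPKM, and 1 lower, Rps27 at 437 and 203 FPKM. Of the oxidative phosphorylation genes 1 was lower, Ndufs5 at 67.6 and 30.8 FPKM. In all, 9 of 26 lists with at least 5 measured members lay outside the central 95% of random lists. Chance alone would put about 1.3 of these 26 there if members of a list varied independently, and more if they vary together. The long non-coding RNA list returned to the 97.1st percentile without the filter on low FPKM, the snoRNA hosts to the 86.9th with a minimum mean FPKM of 5, and the transcription factors to the 95.3rd under quantile normalization, which also took the meiotic prophase list from the 3.73rd to the 1.17th. With a minimum mean FPKM of 5, the meiotic prophase list lay at the 1.6th and the piRNA and transposon control list at the 97.9th. Without the filter on low FPKM, medians relative to that of all genes shrank. They went from 0.75 to 0.30 for early embryonic genes and from 0.92 to 0.40 for histones. For Rik clones they went from 0.23 to 0.062 and for Gm models from 0.15 to 0.023. These lists stayed above the central 95% of matched lists.

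The remaining lists held few 2-fold differences at day 14. In the list of RNA exosome subunits and MTR4 partners, Exosc2, a subunit of the exosome core, stood at 23.8 FPKM in WT and 233 FPKM in Mtr4-null oocytes, and Srrt at 4.98 and 16.8 FPKM, beside the lower Skiv2l2. The interferon regulatory gene Irf9 stood at 0.625 and 22.7 FPKM, the only one of 11 interferon response genes to differ 2-fold. The centromere protector gene Sgol2 stood at 20.1 and 81.2 FPKM, and the cyclin gene Ccnb3 at 7.31 and 2.09 FPKM. The water and glycerol channel gene Aqp9 stood at 13.7 and 4.40 FPKM, the only one of 23 cell volume and ion transport genes to differ 2-fold. None of the 26 maternal effect genes, 13 zona pellucida and oocyte secreted factors, 35 DNA methylation and chromatin regulators, 36 endomembrane trafficking genes or 19 piRNA and transposon control genes differed 2-fold. Examples are Zbed3 at 3175 and 4386 FPKM, Gdf9 at 4247 and 4409 FPKM, Zp3 at 4211 and 4170 FPKM, and Dnmt1 at 216 and 289 FPKM.

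The same question was asked of germinal vesicle oocytes at day 21, where differences of both directions were more numerous. The Mtr4-null mean of day 21 may average fewer libraries than the labels list, which limits this and every later comparison that uses it. Dclre1c reached 3254 FPKM in Mtr4-null against 25.4 FPKM in WT oocytes, AI506816 reached 2710 against 11.1 FPKM, and Lrrc2 reached 1257 against 7.55 FPKM. Rplp2-ps1 stood at 1013 against 6.39 FPKM, Snhg3 at 693 against 5.85 FPKM, and Ccdc48 at 616 against 1.33 FPKM. Mt1 stood at 446 against 1.77 FPKM, Prr11 at 428 against 1.88 FPKM, and Rmrp at 212 FPKM against a listed 0. LOC100861570 was listed at 0 in the other 3 groups and at 406 FPKM in Mtr4-null oocytes at day 21. Among Gm symbols, Gm5531, now the protein-coding gene Teddm1b, stood at 1593 against 6.19 FPKM, and the long non-coding Gm7616 at 882 against 4.03 FPKM.

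Among the lower genes of day 21, the receptor tyrosine kinase inhibitor gene Spry4 stood at 118 FPKM in WT and 4.82 FPKM in Mtr4-null oocytes, and Umodl1 at 282 and 13.8 FPKM. Rgn stood at 67.8 and 3.61 FPKM, Oas1f at 47.8 and 1.36 FPKM, and the chemokine receptor gene Cxcr3 at 22.5 and 0.352 FPKM. The olfactory receptor genes Olfr288 and Olfr287 stood at 48.4 and 15.2 FPKM in WT and at 1.18 and 0.0786 FPKM in Mtr4-null oocytes. Fam25c stood at 28.8 FPKM in WT and was listed at 0 in Mtr4-null oocytes. Gm10094, now the protein-coding gene Sap18b, stood at 1592 and 11.1 FPKM, and 9130015A21Rik at 33.4 and 0.358 FPKM. In all, 2410 genes were higher and 3067 lower. Median-of-ratios scaling moved the median of all genes from -0.27 to 0.05 and the counts to 3028 higher and 1965 lower, a higher share of 60.6% rather than 44.0%, so each list's count below stands beside its median relative to that of all genes.

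The lists that stood above matched random lists at day 14 mostly did so at day 21 as well. Of the 8 early embryonic genes, 6 were higher and 2 lower, with a median 2.74 above that of all genes. Eif1a stood at 4.81 FPKM in WT and 60.8 FPKM in Mtr4-null oocytes, Zscan4c at 0.804 and 17.2 FPKM, Zscan4f at 0.799 and 15.1 FPKM, and Zscan4d at 4.39 and 30.6 FPKM. The Zscan4 copies share much of their sequence, so their values are uncertain. Of 18 snoRNA host genes, 12 were higher and 1 lower, with a relative median of 1.89, and Snhg4 and Snhg9 stood at 113 and 1017 FPKM against 0.499 and 27.6 FPKM. Of 27 histone genes, 17 were higher and 1 lower, with a relative median of 1.72. Hist4h4 stood at 56.9 against 1.23 FPKM and Hist1h4i at 39.0 against 1.71 FPKM. The Rik clones divided into 403 higher and 166 lower, and the Gm models into 103 higher and 78 lower, with relative medians of 0.79 and 0.49. Without the filter on low FPKM, which lets in genes near 0, the relative medians were 0.51 for early embryonic genes, 0.92 for histones and 0.15 for Rik clones, and the Gm list lay at the 48.5th percentile.

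Of 20 genes of the unfolded protein and integrated stress response, 7 were higher and 3 lower, with a relative median of 0.64, or 0.40 without that filter. The transcription factor gene Xbp1 stood at 2.57 FPKM in WT and 44.7 FPKM in Mtr4-null oocytes, the chaperone gene Dnajb9 at 6.48 and 68.8 FPKM, and the kinase gene Eif2ak3 at 1.74 and 12.2 FPKM, whereas Creld2 stood at 297 and 91.0 FPKM. Of the 84 ribosomal protein genes, 6 were higher and 2 lower (19 and none under median-of-ratios scaling), with a relative median of 0.34, or 0.082 without that filter, and Rpl7l1 stood at 18.6 and 863 FPKM and Rpl9 at 32.8 and 278 FPKM. The 76 oxidative phosphorylation genes had a median near that of all genes, at -0.0085 relative to it, with 3 higher and 9 lower. Under median-of-ratios scaling it lay at 0.062, with 4 higher and 2 lower, and without the filter on low FPKM at -0.27. Their list lay at the 97.7th percentile because random lists of equally abundant genes were lower still, and it lay at the 95.3rd under quantile normalization. Its own median of -0.28 was thus below 0. Sdha stood at 76.9 and 21.2 FPKM, and Atp5g3 at 52.0 and 166 FPKM.

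Medians of several lists of oocyte function lay below that of all genes at day 21. Of 35 DNA methylation and chromatin regulators, 15 were lower and 2 higher, with a relative median of -0.63 at the 0.740th percentile of matched lists. This list lay at the 2.61st percentile under quantile normalization and at the 3.03rd without the filter on low FPKM. Random lists were matched on expression alone, and exon number also went with the day 21 difference, as given further below. The de novo DNA methyltransferase gene Dnmt3a stood at 22.1 FPKM in WT and 2.82 FPKM in Mtr4-null oocytes, its cofactor gene Dnmt3l at 140 and 25.9 FPKM, and the histone methyltransferase gene Ezh2 at 144 and 25.6 FPKM. The demethylase gene Kdm5a was higher, at 0.882 and 6.85 FPKM. Of 33 genes of meiotic arrest and resumption, 13 were lower and 1 higher, with a relative median of -0.60 at the 2.71st percentile. The mitotic kinase genes Plk1 and Ttk stood at 135 and 127 FPKM in WT and at 24.3 and 24.0 FPKM in Mtr4-null oocytes, and Ccnb3 at 13.6 and 0.483 FPKM. Sgol2 was the higher one, at 18.9 and 493 FPKM.

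Of 26 maternal effect genes, whose products the early embryo needs, 9 were lower and 2 higher, with a relative median of -0.52 at the 4.76th percentile. Nlrp2 stood at 191 FPKM in WT and 27.3 FPKM in Mtr4-null oocytes, Zar1 at 1151 and 205 FPKM, and the histone chaperone gene Npm2 at 1308 and 309 FPKM, whereas Wdr77 stood at 0.246 and 9.71 FPKM. Of 19 piRNA and transposon control genes, 9 were lower and 4 higher, with a relative median of -0.63 at the 4.25th percentile, including Fkbp6 at 14.7 and 63.4 FPKM and Tdrd1 at 63.8 and 16.1 FPKM. Of 36 endomembrane trafficking genes, 14 were lower and 2 higher, with a relative median of -0.52 at the 5.08th percentile, including Rab7 at 379 and 90.6 FPKM and Eea1 at 16.3 and 3.94 FPKM. Of 13 zona pellucida and oocyte secreted factors, 6 were lower and none higher, with a relative median of -0.60 at the 8.70th percentile, including the growth factor gene Fgf8 at 124 and 22.2 FPKM. Under median-of-ratios scaling lower genes still outnumbered higher ones in these lists, with 11 against 3 chromatin regulators, 7 against 1 meiotic arrest genes, 6 against 2 maternal effect genes, 7 against 4 piRNA pathway genes, 6 against 5 endomembrane genes and 4 against 0 zona pellucida and secreted factors. The meiotic arrest list and the maternal effect, piRNA, endomembrane and secreted factor lists lay inside the central 95% of lists of equally abundant genes, although the former lay at the 2.46th percentile with a minimum mean FPKM of 5. Under quantile normalization the maternal effect and the zona pellucida and secreted factor lists lay below it, at the 0.850th and 1.44th percentiles, as did the oocyte transcription factors at the 1.89th.

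**Figure D3:**
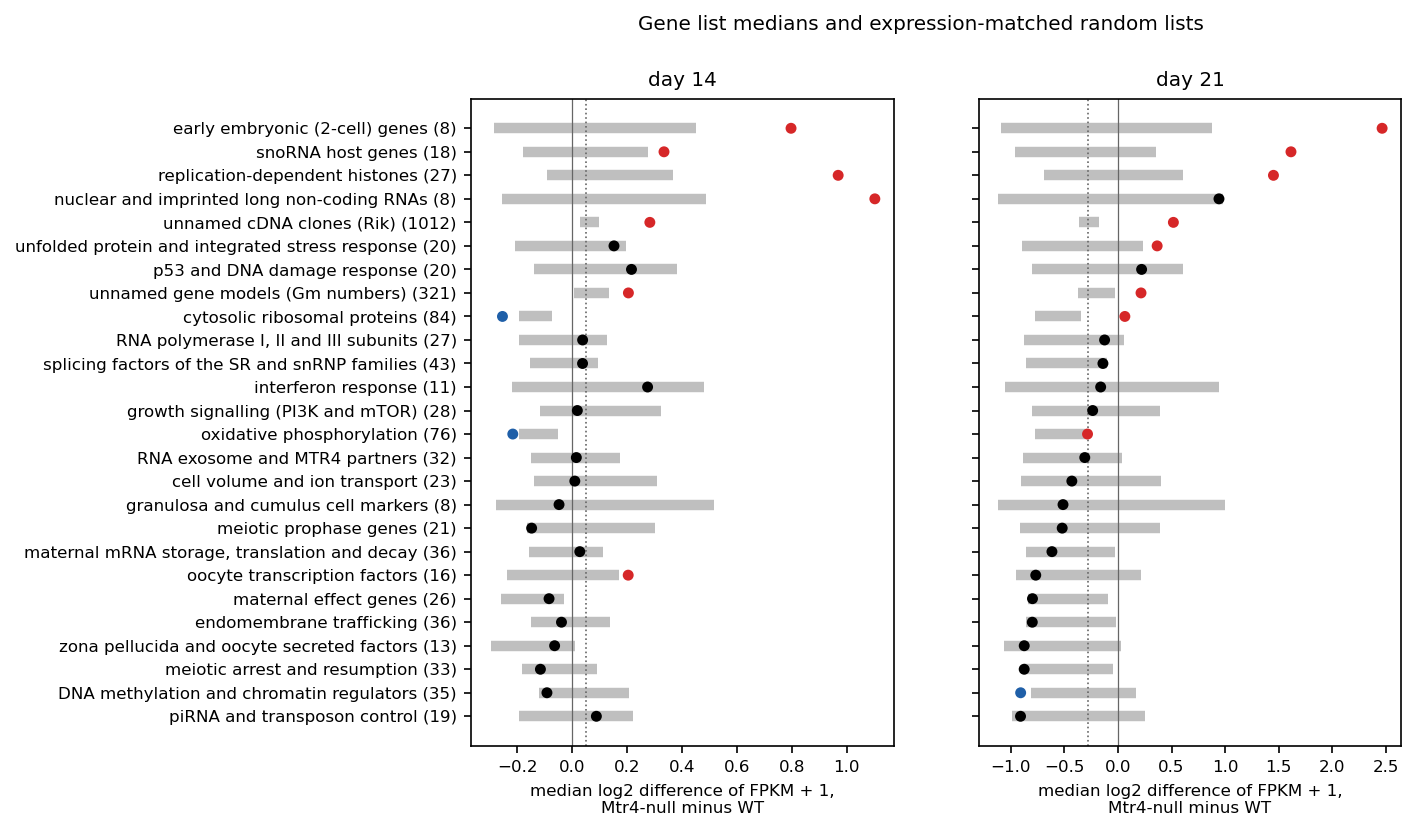
Median log2 difference of FPKM + 1 between Mtr4-null and WT oocytes for 26 gene lists (measured members in brackets) at day 14 and day 21; grey bars span the central 95% of 10000 expression-matched random lists and the dotted line marks the median of all genes. Red and blue points lie above and below the grey bar; the early embryonic list lies farthest above at day 21, the chromatin regulators lie below, and the 2 panels differ in scale.

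The other lists lay inside the central 95% at day 21. Of 32 exosome genes and partners, 5 were higher and 8 lower, with a relative median of -0.034. Under median-of-ratios scaling 5 were higher and 3 lower, with a relative median of 0.024. Exosc2 stood at 20.9 FPKM in WT and 913 FPKM in Mtr4-null oocytes, and Wdr61 at 26.8 and 198 FPKM. The 8 nuclear long non-coding RNAs divided into 4 higher and 2 lower, with a relative median of 1.22, Malat1 at 2.08 and 83.4 FPKM and Pvt1 at 15.9 and 1.85 FPKM, and lay above the central 95% without the filter on low FPKM, at the 98.2nd percentile. Of 36 genes of maternal mRNA storage, translation and decay, 3 were higher and 12 lower (6 and 7 under median-of-ratios scaling), with a relative median of -0.34, Zfp36l2 at 1.73 and 12.8 FPKM and Igf2bp2 at 120 and 26.5 FPKM. Of 16 oocyte transcription factors, 2 were higher and 4 lower (3 and 3 under median-of-ratios scaling, 2 and 8 under quantile normalization). Their relative median was -0.49, with Sohlh1 at 0.662 and 5.48 FPKM and Nobox at 541 and 163 FPKM. Of 23 cell volume and ion transport genes, 1 was higher and 6 lower, with a relative median of -0.15, and Aqp9 stood at 23.5 and 3.34 FPKM. Of 28 growth signalling genes, 3 were higher and 7 lower (5 and 6 under median-of-ratios scaling), with a relative median of 0.040 (-0.041 under quantile normalization). The lower ones included the receptor gene Kit at 85.2 and 29.7 FPKM, and the higher ones the AMP-activated kinase gene Prkaa2 at 5.76 and 53.7 FPKM. Splicing factors, which lay at the 98.0th percentile with a minimum mean FPKM of 5, divided into 8 higher and 8 lower of 43 (9 and 2 under median-of-ratios scaling), RNA polymerase subunits into 5 and 4 of 27, and meiotic prophase genes into 3 and 5 of 21, with relative medians of 0.14, 0.15 and -0.24. Prpf18 stood at 30.6 and 345 FPKM, Polr2l at 171 and 1803 FPKM, and the recombinase gene Dmc1 at 3.72 and 61.1 FPKM. Of 20 p53 and DNA damage response genes, 6 were higher and 3 lower, with a relative median of 0.50. The higher ones included the death receptor gene Tnfrsf10b at 0.253 and 5.07 FPKM and Ccng1 at 3.52 and 16.2 FPKM, and the lower ones Ddit4 at 8.85 and 0.417 FPKM. Of 11 interferon response genes 3 were higher and 2 lower, with a relative median of 0.11 and Irf9 at 0.971 and 131 FPKM.

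Lists of markers of neighbouring ovarian cells were summed to look for other cells in the samples. The 24 granulosa and cumulus cell markers summed to 285 FPKM in WT and 256 FPKM in Mtr4-null oocytes at day 14, and to 243 and 147 FPKM at day 21, with Serpine2 giving 213, 192, 157 and 84.7 FPKM of these. At day 21, 1 of the 8 measured members was higher and 2 were lower, with a relative median of -0.24 and Cyp19a1 at 25.3 FPKM in WT and 1.48 FPKM in Mtr4-null oocytes. The 24 theca, stromal, endothelial and blood cell markers summed to 21.05 FPKM in WT and 16.1 FPKM in Mtr4-null oocytes at day 14, and to 25.01 and 13.5 FPKM at day 21, with 3 members above the filter, of which 1 was higher and 1 lower at day 21. The maternal effect genes summed to 33046 and 33566 FPKM at day 14, and to 31481 and 20181 FPKM at day 21.

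The genotype differences at the 2 ages overlapped. Of the 965 genes higher at day 14, 847 were also higher at day 21, where independent lists of these sizes would share 195. Mt1, AI506816, Lrrc2 and Ccdc48 were among them. Of the 185 lower genes, 151 were also lower at day 21 against 47.6, Rgn and Oas1f among them. Of the 965 genes, 754 differed more at day 21 than at day 14. Across genes, which are not independent replicates, Pearson's r of the differences was 0.65 and Spearman's rho 0.69. Without short RNA loci, a set left out after the data were seen, r was 0.79.

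The WT age comparison followed normal growth, and held fewer 2-fold differences than either genotype comparison. From day 14 to day 21, Pnma5 went from 1.11 to 11.5 FPKM, Bcl2l15 from 0.450 to 6.48 FPKM, the neural adhesion gene Cntn6 from 1.07 to 8.72 FPKM, and the lectin gene Reg3g from 0.931 to 7.22 FPKM. In the other direction, Pxdn went from 6.53 FPKM to a listed 0, Ifi47 from 5.93 to 0.128 FPKM, the germ cell transcription factor gene Sohlh1 from 6.91 to 0.662 FPKM, and H47 from 20.2 to 3.53 FPKM. In all, 241 genes were higher and 396 lower at day 21. With a pseudocount of 0.1 the total was 1282 rather than 637. The lists of splicing factors, chromatin regulators and Gm models lay above matched random lists, and those of maternal effect, meiotic prophase and p53 response genes lay below. At most 1 member of each of these lists differed 2-fold, apart from the Gm models, of which 13 were higher and 6 lower. List positions in the age comparisons and for the difference of genotype effects were computed on the deposited scale alone.

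More genes differed between the ages in Mtr4-null oocytes, whose day 21 mean may average fewer libraries. Zfp872 went from 3.28 FPKM at day 14 to 70.4 FPKM at day 21, Dmc1 from 3.20 to 61.1 FPKM, and Arrdc3 from 2.43 to 49.4 FPKM. Fam84a went from 26.3 to 2.57 FPKM, the thyroid hormone binding gene Crym from 25.7 to 2.58 FPKM, Nlrp2 from 203 to 27.3 FPKM, and Cd177 from 36.5 to 4.24 FPKM. In all, 1082 genes were higher and 2216 lower at day 21. Median-of-ratios scaling gave 1865 higher and 1020 lower, and quantile normalization 1484 and 1595, so the higher share was 32.8%, 64.6% or 48.2%. Of the 241 genes higher with age in WT, 27 were also higher in Mtr4-null oocytes, where independent lists would share 21.9, and 31 were lower against 44.8. Of the 396 lower in WT, 60 were also lower against 73.7, and 64 were higher against 36.0. Across genes, r of the age changes in the 2 genotypes was -0.036. Maternal effect genes (12 lower, 1 higher), zona pellucida and secreted factors (7 lower) and piRNA pathway genes (9 lower) lay below matched lists. Among the 9 lists above them were the snoRNA hosts (13 higher of 18), the early embryonic genes (5 higher, 1 lower) and the ribosomal protein genes (8 higher, 1 lower).

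The genotype difference itself differed between the ages for many genes. Zfp872 stood at 1.16 FPKM in WT and 3.28 FPKM in Mtr4-null oocytes at day 14, and at 0.478 and 70.4 FPKM at day 21. The mitochondrial import gene Tomm5 stood at 9.08 and 26.2 FPKM at day 14 and at 1.60 and 125 FPKM at day 21, Rin1 at 2.25 and 13.3 FPKM and then at 1.19 and 167 FPKM, and Amd2 at 2.68 and 8.45 FPKM and then at 0.0281 and 51.1 FPKM. Spry4 stood at 57.7 and 36.3 FPKM at day 14, before the gap given above for day 21, and Cd177 at 57.4 and 36.5 FPKM and then at 76.6 and 4.24 FPKM. Emilin2 stood at 8.71 and 10.5 FPKM and then at 18.6 and 1.07 FPKM. The log2 genotype difference was at least 1 higher at day 21 for 1618 genes and at least 1 lower for 2672. Median-of-ratios scaling gave 2428 and 1416, and quantile normalization 1952 and 2057, which takes the higher share from 37.7% to 63.2% or 48.7%. The maternal effect and piRNA lists lay below matched lists on this measure, and 7 lists lay above them, including the snoRNA hosts, early embryonic genes and ribosomal protein genes.

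Short RNA loci, such as miRNA and snoRNA genes, gave the largest differences under the naming rule. Mir484, Mir1956 and Mir1894 were listed at 0 in WT at both ages, and stood at 2190, 2109 and 1180 FPKM in Mtr4-null oocytes at day 14 and at 22143, 5974 and 4347 FPKM at day 21. Snord85 was likewise listed at 0 in WT and stood at 414 and 2240 FPKM. Snord91a, Scarna17 and Snord57 stood at 844, 604 and 551 FPKM in Mtr4-null oocytes at day 14 and were listed at 0 in the other groups. In the other direction, Mir678 stood at 476 FPKM in WT at day 14 and near 0 in Mtr4-null oocytes, and Mir5116 at 314 and 0.0971 FPKM at day 21. Of 738 such loci, 166 passed the filter, which a locus listed at 0 in WT can pass through its Mtr4-null values alone. Among these 166, 94 were higher and 23 lower at day 14, and 84 and 18 at day 21. These counts are therefore partly selected by the difference they describe. Such loci can lie within longer genes, and an FPKM divides by a very short length, so they were kept out of the lists and the named genes above.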

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

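The test of stray reads was chosen after the values were seen; the test of nearby promoters was fixed before, but the resampling range used to read it was added after its value was seen. A poly(A) library is not meant to measure short RNA loci, yet these loci carried 31513 summed FPKM in Mtr4-null oocytes at day 14 against 13427 in WT, and 87179 against 13038 at day 21. That is 5.29% and 13.4% of all FPKM in Mtr4-null oocytes, and 2.24% and 2.16% in WT. Stray reads over very short loci stay open: 24 loci were above 0 in both Mtr4-null means and in no WT mean, against 1 the other way round, a ratio of 24, but this restates the pattern and excludes nothing. Reads of longer transcripts that begin at coding promoters could also cover such loci, and the 15 loci within 1 kb of a coding start differed from the 147 others by -0.11 in median log2 difference at day 21. The range over 1000 resamplings of the loci was -2.93 to 7.96, so this explanation stays open too.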

How the results depend on the processing

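Leaving out short RNA loci, and some settings for lists, correlations and the targeted gene, were chosen after seeing the data. No paired analysis was possible because the table holds only group means, and for the same reason the planned limma and camera fits, the refits without single libraries and the spike-in scaling were not run. The 5 counts of genes stayed within 1.5 times under every setting, except that a pseudocount of 0.1 took the genotype count at day 14 from 1150 to 1740 and the WT age count from 637 to 1282, because low genes then pass 2-fold more easily. The split into higher and lower genes was less stable, as given with each comparison. The correlation of genotype effects was 0.65, ranged from 0.62 to 0.65 under the other scalings, filters and pseudocount, and was 0.79 without short RNA loci; that of age changes ranged from -0.041 to -0.027. Skiv2l2 stayed lower at both ages and moved by less than 1.5-fold under each setting run. Between 8 and 10 lists lay outside the central 95% at day 14 and between 8 and 12 at day 21. Of 18 such pairs of list and age, 12 were outside under every setting. The oxidative phosphorylation list at day 21, at -0.0085 relative to all genes, turned to 0.032 with a pseudocount of 0.1, 0.13 with a minimum mean FPKM of 5 and 0.062 under median-of-ratios scaling. Without the filter on low FPKM it went the other way, to -0.27. The cause was not tested. Of 992 recomputed values of named genes, 945 moved by less than 1.5-fold and 47 by more. None of the differences of at least 2-fold changed sign, and the sign of smaller ones was not checked.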

Other observations

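Among protein-coding genes, the median log2 difference between Mtr4-null and WT oocytes at day 21 was 0.10 for 598 single-exon genes, 0.16 for 725 genes with 2 exons and 0.015 for 1778 genes with 3 or 4 exons. It was -0.29 for 2730 genes with 5 to 8 exons, -0.48 for 3105 genes with 9 to 16 and -0.70 for 1971 genes with 17 or more. At day 14 the same medians ran from 0.18 for single-exon genes to 0.0081 for those with 17 or more. The exon and expression groups were formed after the data were seen. The day 21 trend had the same order from 2 exons upwards under median-of-ratios scaling (0.53 to -0.39) and quantile normalization (0.20 to -0.76). Within the middle of 5 bins of exonic length it ran from -0.028 for 622 genes with up to 4 exons to -0.86 for 296 genes with 17 or more. Expression also went with the day 21 difference, with medians from 0.065 in the lowest to -0.52 in the highest of 5 bins of mean log2 expression. Within the lowest bin the medians ran from 0.74 for genes with up to 4 exons to -0.34 for those with 17 or more, within the middle bin from 0.18 to -0.89, and within the highest from -0.26 to -0.97. No random list was matched on exon number. How far the day 21 positions of the gene lists, maternal effect genes included, follow exon number was not tested.

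A scan of 89 symbol stems with at least 12 measured members was made after the data were seen. It placed 10 outside the central 95% of matched random lists at day 14 and 23 at day 21. Chance would give 4.45 if members of a family varied independently, and more if they vary together. Of 288 zinc finger genes with Zfp symbols, 40 were higher and 1 lower at day 14, and 102 were higher and 35 lower at day 21, with a median 0.69 above that of all genes other than short RNA loci. Of 13 Zscan genes, some of which are also in the early embryonic list, 8 were higher and 1 lower at day 21. The 20 F-box genes with Fbxw symbols went the other way, with 12 lower and 1 higher at day 21 and a median 1.26 below that of all genes (-1.26). Of 45 ubiquitin peptidase genes with Usp symbols, 20 were lower and 4 higher. These medians kept their sign relative to all genes under both other scalings. Members of a family can be near identical, so reads may be shared.

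For the 2 patterns below, the tests of the day 21 mean, of scaling and of follicle cells, the percentiles beyond the first for abundant mRNAs, and for delayed growth the resampling and the comparison of the list with WT of day 14, were chosen after the results were seen. The first pattern is the higher level of long non-coding genes in Mtr4-null oocytes. Noise of low-abundance genes and gene length bias would leave the median within the range of random lists. However, it lay at the 100th percentile at both ages, whether matched on expression or on expression and exonic length (536 of 587 genes with a length, 91.3%). Only genes past the filter on low FPKM entered these matches. The matching used mean expression over all 4 groups, Mtr4-null values included, and left out exon number. Genes low in WT were thus not compared with genes equally low in WT, so noise of such genes is not excluded. A fault of the day 21 mean, which may average fewer libraries, would not show at day 14, where long non-coding genes lay 0.61 above other genes. A candidate biological explanation is loss of turnover of transcripts divergent from coding promoters: the 177 long non-coding genes that start within 1 kb of a coding gene on the opposite strand had a median of 2.02 at day 21, at the 100th percentile of expression-matched draws from the others. This remains a hypothesis, since unstranded reads of the coding neighbour may count towards such genes and group means carry no replicate error.

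The second pattern is the lower level of maternal effect genes at day 21. Follicle cells mixed into the samples would raise their markers, but the log2 ratio of summed granulosa marker FPKM, Mtr4-null to WT, was -0.72. That sum rests mainly on Serpine2, at 157 of 243 FPKM in WT and 84.7 of 147 FPKM in Mtr4-null oocytes, and Cyp19a1 fell too. Of the 8 measured markers, 1 was higher, 2 were lower and 5 stayed within 2-fold. The ratio thus says little about the other markers and does not decide the question. Delayed growth would place Mtr4-null oocytes of day 21 nearer to WT of day 14. The SD of the differences was indeed 0.923 times that against WT of day 21 (0.916 to 0.930 over 1000 resamplings of genes). That range does not cover variation between samples, since genes are not independent replicates. The gap was smaller than the bound set beforehand, but this cannot decide the question. The WT change with age had an SD of only 0.48, beside 1.54 for Mtr4-null against WT at day 21. Even a full delay therefore need not reach the bound. The list itself was farther from WT of day 14, at -1.09, than from WT of day 21, at -0.80. A general fall of abundant mRNAs stays open. The list lay at the 4.76th percentile of equally abundant genes, inside the central 95%, but at the 0.850th under quantile normalization. It lay at the 0.580th for the difference of genotype effects and at the 0.140th for the age change in Mtr4-null oocytes, beside the 0.200th for that in WT. All of these but the last rest on the same Mtr4-null mean of day 21, so they are not independent. Scaling stays open for the level itself, with list medians of -0.40 under median-of-ratios scaling and -0.95 under quantile normalization; these do not test the place of the list among genes, which was -0.52 relative to all genes on the deposited scale, -0.45 and -0.68.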
